A study of Mus musculus with 5 samples.

How the data were processed

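Gene expression was measured by RNA sequencing in 5 libraries of mouse embryonic fibroblasts during reprogramming, 2 at day 4 and 3 at day 8. Per the labels' protocols, RNA was taken with Trizol and libraries were made with the TruSeq RNA kit from 1 ug of total RNA. Bowtie2 version 2.2.5 and the mm10 genome were used, per the submitters' processing notes. The program that counted reads per gene, and its annotation, are not given in the sources used here. Per the file headers, the deposited files hold an expected count, a TPM and an FPKM for each gene, with an average transcript length and an effective length. The deposited TPM summed to 1000000 in each library, and between 16.8% and 19.0% of the 29267 deposited expected counts of a library, zeros included, had a nonzero fractional part (no tolerance). The deposited FPKM column was used for library sums alone.

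Gene IDs were matched to the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Of 29267 IDs 28756 (98.2%) had a symbol there, and the 511 without one stayed in the tables without a name. Mitochondrially encoded mRNAs and ribosomal protein genes were not analysed here as lists. Expected counts were rounded to whole counts. They were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.02 for the day-8 control, 1.01 for mastoparan, 0.951 for paraquat, 1.01 for Flag and 1.01 for CypD. The log2 ratio of a gene is that of scaled CPM (counts for each 1000000 reads of the TMM-scaled library) with a pseudocount of 0.5 CPM, for genes with a mean of at least 1 CPM over the libraries of that day. Folds are ratios of scaled counts with no pseudocount, and their 95% intervals are exact Clopper-Pearson intervals of the share of counts in the first library. Reads from amplified libraries are not independent molecules, so these intervals and floors cover counting error only. The intervals are not adjusted for choosing the most extreme of many genes. Where a library had 0 counts, the fold is a bound against a floor of 3 counts per library. Statistics were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

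The comparisons were CypD against Flag at day 4, and mastoparan against control, paraquat against control and mastoparan against paraquat at day 8. With 1 library per group there is no test between conditions and no p-value. Counts of genes past 2-fold were set beside the mean of 100 simulations in which both libraries share 1 set of levels and differ by Poisson noise alone. For each of 34 gene lists with at least 3 measured members, 32 in all, the median log2 ratio was given an order-statistic 95% interval over members, or the range where a list had at most 5 measured members, too few for such an interval. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Members past 1.5-fold were counted, and set beside the mean number in the random lists. The 2 day-8 comparisons with the same control were simulated with counting noise alone and with a further coefficient of variation of 0.2.

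Named genes follow a rule with 3 parts. Ppif, Pou5f1, Sox2, Klf4, Myc, Nanog and Tet2 are always reported. The 10 highest and 10 lowest log2 ratios among genes with a mean of at least 5 CPM over the libraries of that day are named, except for predicted genes, clone names and bare IDs. Up to 4 members per list with the largest absolute log2 ratio are named. Some genes that the rule takes are not reported here. The comparisons, lists, naming rule, filter, pseudocount and most alternatives were chosen before the data were examined. Added after seeing the data were the removal of trends along transcript length (medians of 40 length bins subtracted) and GC content, and the leaving out of genes that share at least 20% of their 49-base windows with another gene. The naming of the 10 highest and lowest genes under that 20% limit, and a comparison of the day-8 control with the Flag library for the closing section, were also added after seeing the data. The windows were counted in the reference sequences of 82533 of the 84205 transcripts in the files.

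The other settings tried were library totals alone, size factors from DESeq2 1.42.0, upper-quartile factors, deposited TPM, no filter or a minimum of 5 CPM, pseudocounts of 0.1 and 2 CPM, and leaving out the 20 most abundant genes with mitochondrial and rRNA genes. The code was tested on simulated data made from 29267 genes with 50 genes at each of several true folds. A true 4-fold difference passed 2-fold in 100% of the genes in each comparison. A true 3-fold difference passed in 98.0% for CypD against Flag, 96.0% for mastoparan against control, 100% for paraquat against control and 96.0% for mastoparan against paraquat. For a true 2-fold difference these shares were 50.0%, 54.0%, 42.0% and 44.0%, and the intervals held the true fold for 97.0%, 94.5%, 95.5% and 93.5% of changed genes. A count of 1 CPM stands for 3.08 reads in the day-8 control, 2.85 in the mastoparan, 2.31 in the paraquat, 2.53 in the Flag and 3.45 in the CypD library.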

Results

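RNA was sequenced from mouse embryonic fibroblasts of the ICR strain during reprogramming. There were 5 groups with 1 library each, so no difference below has a replicate check. Intervals of folds and counts cover counting error only. Those of medians or shares over genes describe the spread between genes, not between libraries. At day 4 a library from cells expressing CypD (cyclophilin D, the mitochondrial permeability transition regulator encoded by Ppif) stood beside a Flag control. At day 8 libraries from cells treated with mastoparan, a wasp-venom peptide, or paraquat, a redox-cycling herbicide, stood beside an untreated control. The series title gives the question as which genes are regulated by the mitoflash, a brief burst of superoxide and pH signal in a mitochondrion. Doses and the set of introduced factors were not given in the sources used here. The total expected count was 2497736 in the Flag library, 3426702 in the CypD library, 3016439 in the day-8 control, 2834186 in the mastoparan library and 2426015 in the paraquat library. A floor of 3 counts equals 1.18, 0.869, 0.973, 1.05 and 1.30 CPM in the same order. Across 11069 genes, which are not independent replicates, Pearson's r was 0.984 between the day-4 libraries. At day 8 it was 0.983 for control and mastoparan, 0.968 for control and paraquat, and 0.969 for mastoparan and paraquat.

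Ppif (ENSMUSG00000021868; mm10 chromosome 14, 25694154 to 25700468, plus strand) checks the CypD label. It had 2629 counts in the CypD library and 112 in the Flag library, which is 761 and 44.2 CPM (counts for each 1000000 reads of the TMM-scaled library). In the day-8 control, mastoparan and paraquat libraries it had 90, 95 and 79 counts, or 29.2, 33.3 and 34.2 CPM. The genotype label names CypD expression for all 3 day-8 libraries, the series design text does not, and none of the 3 had Ppif above the Flag library. The day-8 comparisons below therefore rest on the treatment labels alone. The other genes fixed in advance lie, on mm10, at chromosome 17, 35506018 to 35510772 (Pou5f1), chromosome 3, 34650405 to 34652461 (Sox2), chromosome 4, 55527143 to 55532466 (Klf4), chromosome 15, 61985391 to 61990374 (Myc), chromosome 6, 122707489 to 122714633 (Nanog) and chromosome 3, 133463679 to 133545139 (Tet2).

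**Figure D1:**
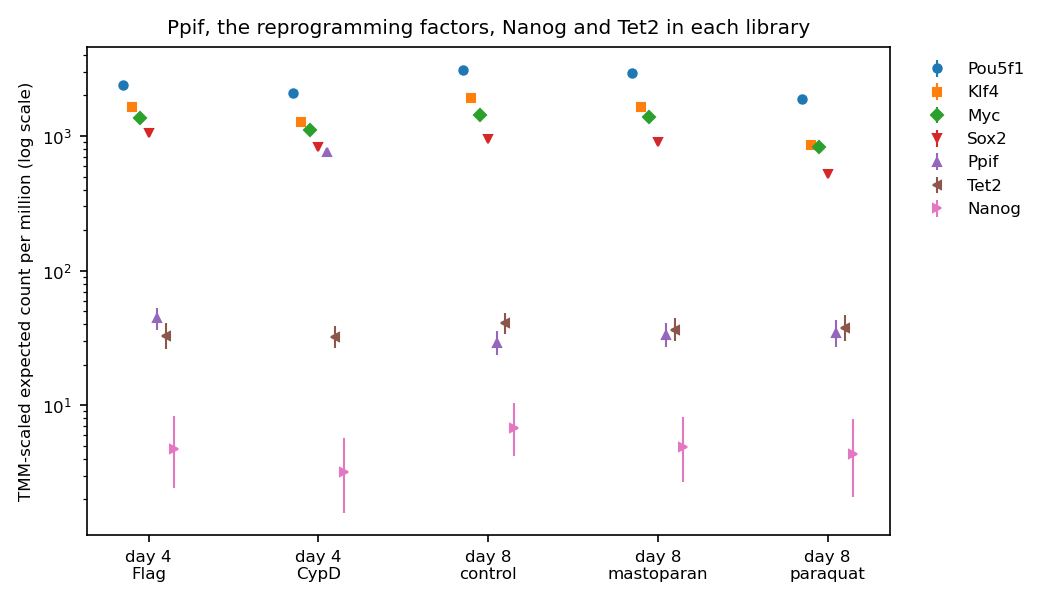
Level of 7 genes in each of the 5 libraries, as TMM-scaled expected counts (CPM) on a log axis, with bars for the 95% exact Poisson interval of the count and 1 library per group. Ppif stands at 761 CPM in the CypD library and between 29.2 and 44.2 in the others, and Klf4 stands at 860 CPM in the paraquat library against 1901 in the day-8 control.

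The first comparison asks which genes differ when CypD is expressed for 4 days of reprogramming. Ppif itself was 17.2-fold higher in the CypD library (95% interval 14.3 to 21.0), a log2 ratio of 4.09. Among genes with little sequence shared with others, the next was Cxcr2, a chemokine receptor (mm10 chromosome 1, 74153989 to 74161246), with 64 against 10 counts (4.70-fold higher, 2.4 to 10.3). Dtx4, a ubiquitin ligase of the Notch pathway, had 36 against 9 counts (2.94-fold higher, 1.39 to 6.93). The zinc finger gene Zfp870 was 2.54-fold higher (1.41 to 4.87), and the mitochondrial translation release factor gene Mtrf1 had 37 against 10 counts. On the lower side, Prkcz, an atypical protein kinase C, had 11 against 25 counts (3.10 times lower in the CypD library, 1.47 to 6.97). Me3, a mitochondrial malic enzyme, was 2.83 times lower (1.41 to 5.97), and the transcriptional cofactor gene Dach1 had 9 against 20 counts. At 5 CPM or more, the level used for naming, 72 genes passed 2-fold against a mean of 33.3 from counting noise alone. Only 19 higher and 23 lower were among the 9925 genes with under 20% of shared sequence, where all genes named here lie. The noise mean covers all 10759 genes at that level. Many of the genes named beside Ppif may thus differ by counting error alone.

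All 4 of the usual reprogramming factors were lower in the CypD library, with a median log2 ratio of -0.31 (range -0.37 to -0.20 over the 4 genes) that lay at percentile 0.00 of expression-matched random lists. Klf4 was 1.29 times lower (1.24 to 1.35), Sox2 1.27 times lower (1.20 to 1.34), Myc 1.22 times lower (1.16 to 1.27) and Pou5f1 1.15 times lower (1.11 to 1.19). Introduced and endogenous copies of these genes cannot be told apart in the gene tables. Of 23 measured immediate-early genes, which respond within minutes to growth factors and stress, 18 had a log2 ratio below 0, with a median of -0.14 (interval -0.20 to -0.09) at percentile 0.11. Examples are the nuclear receptor gene Nr4a1 (594 against 539 counts, log2 ratio -0.31) and the MAP kinase phosphatase gene Dusp5 (-0.31), and no member was past 1.5-fold. Of 48 nuclear-encoded genes of the respiratory chain and ATP synthase, 37 lay above 0 (median 0.12, interval 0.04 to 0.13, percentile 100), such as Atp5h at 0.29 and Uqcrb at 0.25. Of 40 fibroblast genes 27 lay below 0 (median -0.06, percentile 1.67). With the trend along transcript length removed, the respiratory chain median was 0.01 (percentile 44.3) and the fibroblast median 0.00 (percentile 41.8). The mitochondrial dynamics and biogenesis genes were split, 11 above and 10 below 0, with a median of 0.10 (interval -0.18 to 0.21, percentile 98.8); the nuclear receptor gene Esrra was at 0.42, the mitochondrial DNA packaging factor Tfam at 0.32 and the inner-membrane protease Oma1 at -0.49. That median was 0.06 (percentile 89.2) with the length and GC trends removed and 0.04 (percentile 88.8) with a minimum of 5 CPM. The 6 histone genes without poly(A) tails had a median of 0.32 (percentile 97.95, or 92.8 with the length trend removed) from few counts and shared sequence. Among permeability transition and mitochondrial calcium genes, Ppif was the only one of 21 past 1.5-fold, and the median of the list was 0.08 (percentile 96.4). Of 22 interferon-stimulated genes, 6 were at least 1.5-fold higher and 2 lower, where matched random lists held 3.09 and 3.03 on average. Nanog, with 11 against 12 counts, and the DNA demethylase gene Tet2, with 111 against 83, had intervals on both sides of no difference.

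Across 13244 genes, 251 were at least 2-fold higher in the CypD library and 252 at least 2-fold lower, while counting noise alone gave means of 220 and 168. The even split depended on the setting, with 278 higher and 408 lower on deposited TPM, and 836 and 654 with no filter. At 20 CPM or more, 8 of 7841 genes passed 2-fold against 0.07 from noise. Only 1 higher gene, Ppif itself, and 1 lower gene of these had under 20% of shared sequence. The spread (SD) of log2 ratios at that level was 0.20 against 0.17 from noise. Some large ratios were in genes that share sequence: Nanp, a sialic acid phosphatase, had 62 against 1 counts but a log2 ratio of 0.41 when summed with its near copy, Btg3 was at 2.65 and -0.08 when summed, and Galnt2 was at -1.95 and -0.12 when summed. Of 20 genes named as highest or lowest, 8 share at least 20% of their sequence windows and are uncertain. Of 32 gene lists, 6 lay outside the central 95% of random lists, against 1.6 if list members varied independently, as random genes would. That number takes no account of variation between replicate libraries, which was not measured. The medians of the other 26 lists ranged from -0.19 to 0.28.

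**Figure D2:**
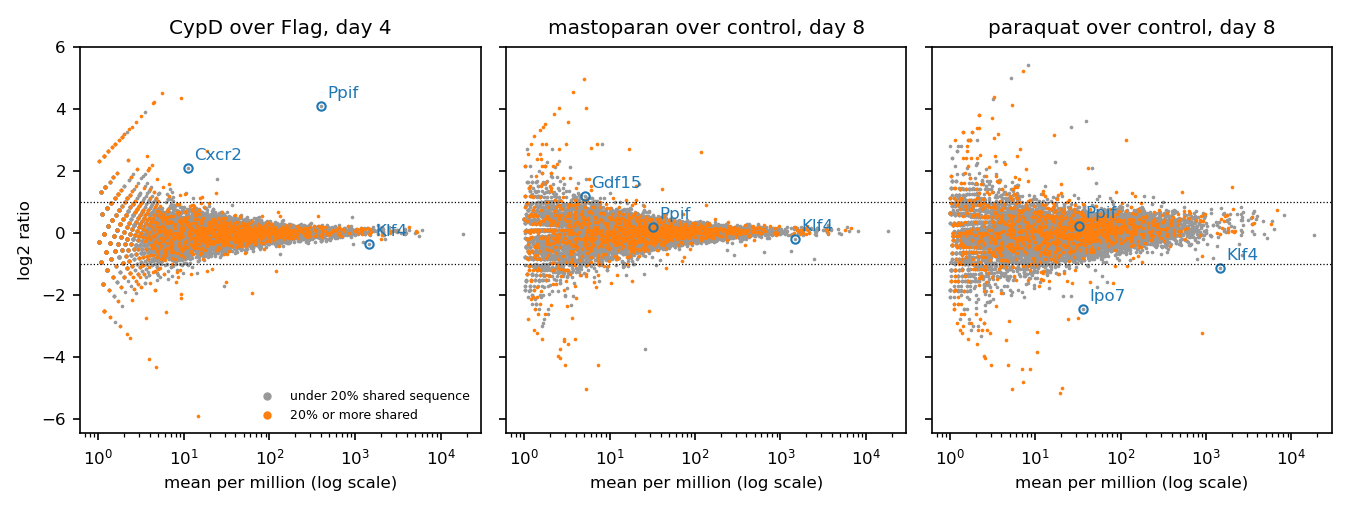
Each point is a gene, with its mean level CPM over the libraries of that day on a log axis and its log2 ratio on the vertical axis, for CypD over Flag, mastoparan over control and paraquat over control; dotted lines mark 2-fold, and orange marks genes that share at least 20% of their sequence with another gene. Ppif stands apart at 4.09 in the CypD panel, and the cloud is broader for paraquat, with an SD at 20 CPM or more of 0.34 against 0.20 for CypD and 0.19 for mastoparan.

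The second comparison asks what differs after mastoparan treatment to day 8. Gdf15, a secreted stress cytokine, had 25 counts in the mastoparan library and 11 in the control (2.46-fold higher, 1.17 to 5.54). Rtn4ip1, a mitochondrial oxidoreductase, had 38 against 16 counts (2.57-fold higher, 1.40 to 4.94), and the F-box gene Fbxl22 had 22 against 6 (3.97-fold higher, 1.56 to 12). Adcy3, an adenylyl cyclase, had 27 against 77 counts (2.64 times lower in the mastoparan library, 1.68 to 4.25). The aggrecan-cleaving protease gene Adamts5 was 2.43 times lower (1.34 to 4.62), and the posterior patterning gene Hoxc10 was 3.0 times lower (1.32 to 7.68). Fam221b had 0 counts against 19 in the control, which is at least 5.85-fold lower against a floor of 3 counts. Adcy3 and Fam221b share 18.7% and 13.2% of their sequence windows with other genes, so their values are uncertain. At 5 CPM or more, the level used for naming, 73 genes passed 2-fold against a mean of 38.0 from counting noise alone. Some of these named genes may thus differ by counting error alone.

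The reprogramming factors lay near the control, with a median log2 ratio of -0.07 (range -0.21 to -0.06, percentile 1.80). Klf4 was 1.16 times lower (1.11 to 1.20), and Pou5f1, Sox2 and Myc had log2 ratios of -0.06, -0.06 and -0.07. Nanog had 14 against 21 counts, Tet2 a log2 ratio of -0.16 and Ppif one of 0.19, each with an interval on both sides of no difference. Of 35 S-phase genes 23 lay above 0 and none was past 1.5-fold, with a median of 0.10 at percentile 99.5 and an interval of -0.00479 to 0.12 that holds 0. Among them were the DNA primase gene Prim1 at 0.37 and thymidylate synthase, Tyms, at 0.35. Of 22 immediate-early genes 17 lay below 0 (median -0.11, interval -0.24 to -0.03, percentile 0.31), with Etv4 at -0.47 and Fosb at -0.45 against Egr2 at 1.22 from 17 against 7 counts. Of 21 mitochondrial dynamics and biogenesis genes 16 lay below 0 (median -0.11, interval -0.27 to -0.01, percentile 1.16), with Oma1 at -0.71 from 38 against 68 counts and the mitochondrial fusion gene Mfn2 at -0.46 from 81 against 121. Genes of the NRF2 and oxidative-stress response had a median of 0.08 (22 of 35 above 0, interval -0.00579 to 0.11 that holds 0, percentile 98.5), with the carbonyl reductase gene Cbr3 at 0.53, and the respiratory chain one of 0.08 (39 of 48 above 0, percentile 99.7), with Cox6b1 at 0.29. With the length trend removed, the NRF2 and respiratory chain percentiles were 94.4 and 82.7, and with both the length and GC trends removed the NRF2 and immediate-early lists lay at percentiles 84.7 and 3.11. Neural and glial markers had a median of 0.46 (interval 0.01 to 0.92, percentile 99.98) with 5 of 11 members at least 1.5-fold higher against a mean of 1.07 in matched random lists, all from few counts, such as Sox1 with 17 against 9 and Elavl4 with 7 against 4. Paraquat against the same control had 4 of 11 such members (median 0.27, percentile 94.1), and mastoparan against paraquat lay at percentile 79.1. The immediate-early list had medians of -0.13 (percentile 4.70) and 0.04 (percentile 72.2) in those 2 comparisons. The part of the shared control library in these values cannot be split off. In the integrated stress response list Gdf15 stood against Ddit3 at -0.46 and Chac1 at -0.77, and the list median was 0.03 (percentile 59.1).

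Across 13651 genes, 213 were at least 2-fold higher in the mastoparan library and 304 at least 2-fold lower, against means of 190 and 208 from counting noise. At 20 CPM or more, 10 of 7903 passed 2-fold against 0.28 from noise, but only 0 higher and 3 lower of these had under 20% of shared sequence. Of the 20 genes named as highest or lowest, 10 share at least 20% of their sequence windows. Lsm7, for example, had 26 against 168 counts but a log2 ratio of 0.22 when summed with its near copy. Of 32 lists 7 lay outside the central 95% of random lists, against 1.6 if list members varied independently, and the other 25 had medians from -0.42 to 0.31. On deposited TPM 2 of those 7 were outside, the reprogramming factors and the immediate-early genes, while the S-phase, mitochondrial dynamics, NRF2, respiratory chain and neural lists lay at percentiles 94.8, 4.96, 91.0, 88.0 and 94.5. With a minimum of 5 CPM the neural list had a median of 0.20 (percentile 97.4).

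The third comparison asks the same of paraquat, and here the differences were larger. All 4 reprogramming factors were lower in the paraquat library. Klf4 had 1985 against 5861 counts (2.21 times lower, 2.10 to 2.33), Sox2 was 1.80 times lower (1.68 to 1.92), Myc 1.75 times lower (1.65 to 1.84) and Pou5f1 1.64 times lower (1.59 to 1.71). Ipo7, a nuclear import receptor (mm10 chromosome 7, 110018274 to 110056609), had 20 against 155 counts (5.80 times lower, 3.63 to 9.76).

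Other genes with under 20% of shared sequence were higher in the paraquat library: Fam221b with 165 against 19 counts (11.6-fold, 7.20 to 19.8), the ciliary gene Rpgrip1 with 201 against 62 (4.33-fold, 3.24 to 5.85) and the myosin gene Myo1h with 77 against 20 (5.14-fold, 3.11 to 8.88). Rbm8a2 had 49 counts against 0, at least 21.8-fold higher against a floor of 3 counts. Rbm8a2, Fam221b, Myo1h and Rpgrip1 share 16.6%, 13.2%, 19.4% and 7.75% of their sequence windows with other genes, so their values are uncertain. Lower were the zinc finger gene Zfp146 (4.27 times, 2.64 to 7.25), Ccdc88c, a scaffold of Wnt signalling (4.26 times, 2.60 to 7.34), the centrosome gene Cep128 with 6 against 39 counts, the kinesin gene Kif13b with 4 against 26 and the nucleoporin gene Nupl1 with 5 against 29.

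By list, the factors had a median log2 ratio of -0.82 (range -1.14 to -0.72 over the 4 genes, percentile 0.01). The pluripotency network list did not share this difference, with a median of -0.08 over 21 measured genes (interval -0.25 to 0.12, percentile 38.5). In it 3 genes were at least 1.5-fold higher and 3 lower, where matched random lists held 2.80 and 3.54 on average. Nanog had 10 against 21 counts with an interval of 0.71 to 3.74 times lower, and Tet2 and Ppif had log2 ratios of -0.12 and 0.23, so for these 3 genes a difference was not detectable at this depth. Of 35 NRF2 and oxidative-stress genes 23 lay above 0 and 3 were at least 1.5-fold higher: Cbr3 at 0.91, the glutathione transferase gene Gstp1 at 0.65, which shares 62.5% of its sequence windows, and the glutathione peroxidase gene Gpx4 at 0.63. Matched random lists held a mean of 2.27 such genes, and with the length trend removed 1 member was at least 1.5-fold higher. The median of that list was 0.21 (interval -0.03 to 0.33, percentile 99.3), 0.11 with the length trend removed (percentile 98.0) and -0.19 on deposited TPM (percentile 25.6), where the median of all genes was -0.29. Respiratory chain and ATP synthase genes were above 0 in 44 of 48 cases, 10 of them at least 1.5-fold higher against a mean of 3.01 in matched random lists, with Ndufa2 at 0.92 (753 against 530 counts) and Ndufc1 at 0.82. Their median of 0.42 (interval 0.35 to 0.51, percentile 100) was 0.04 (percentile 55.1) with the length trend removed, when 0 members were past 1.5-fold. Fibroblast genes were below 0 in 26 of 40 cases (median -0.13, interval -0.22 to 0.01, percentile 0.39), with the matrix proteoglycan gene Dcn at -0.86 from 30 against 74 counts and the collagen gene Col5a2 at -0.61. Polycomb and chromatin regulators were below 0 in 22 of 26 cases (median -0.16, percentile 1.30), with the histone demethylase gene Kdm4c at -0.80 and the histone methyltransferase gene Ehmt1 at -0.77. Hypoxia targets had a median of -0.12 (percentile 2.04), with the angiogenic factor Vegfa at -0.63 from 185 against 382 counts and Adm at -1.10. With the length trend removed, the fibroblast, Polycomb and hypoxia lists lay at percentiles 8.50, 9.49 and 6.67, and with both the length and GC trends removed at 2.26, 15.7 and 9.79. Of 39 G2/M genes 5 were at least 1.5-fold lower, against a mean of 1.24 in matched random lists, and the list lay at percentile 5.71. Among them were the mitotic kinesin gene Kif11 at -0.84 and the kinetochore gene Cenpf at -0.72. With the length trend removed 3 were at least 1.5-fold lower, for which no random-list mean is given here. Epithelial genes went both ways, with the claudin gene Cldn7 at 1.19, the protease gene Prss8 at -1.50 and a median of 0.00.

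**Figure D3:**
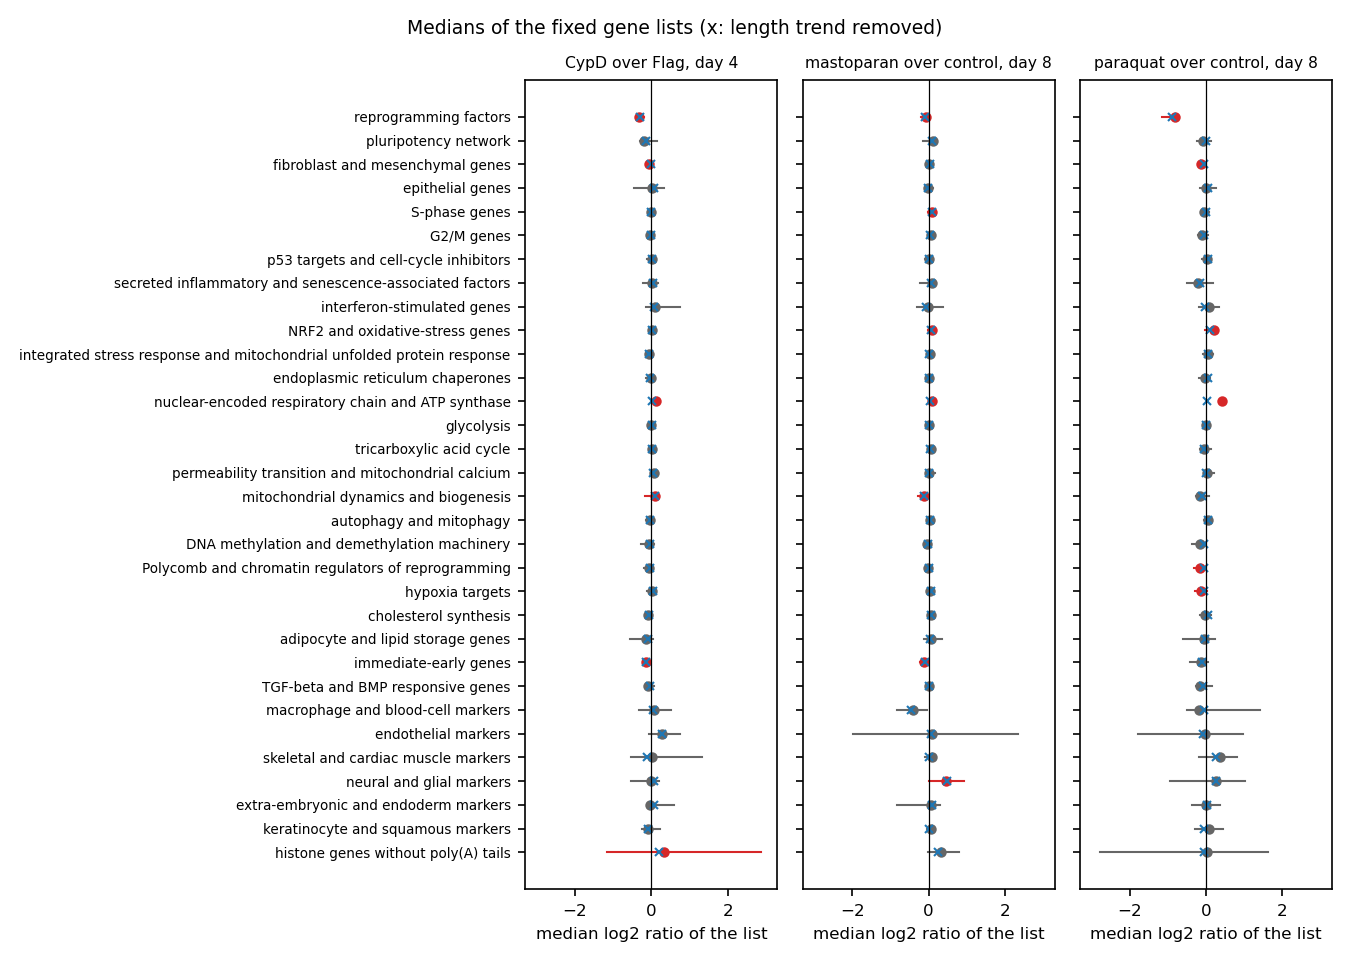
Median log2 ratio of each of 32 gene lists for CypD over Flag, mastoparan over control and paraquat over control, with bars for the 95% order-statistic interval over members (the range in lists of at most 5), red for lists outside the central 95% of expression-matched random lists, and a cross for the median with the length trend removed. The reprogramming factors stand at -0.82 for paraquat, with -0.90 when the trend is removed, while the respiratory chain list goes from 0.42 to 0.04.

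Across 13651 genes, 325 were at least 2-fold higher in the paraquat library and 479 at least 2-fold lower, against means of 198 and 265 from counting noise. At 20 CPM or more the counts were 23 and 28 against 0.24 in all from noise, and the SD of log2 ratios was 0.34 against 0.18. With under 20% of shared sequence the counts at that level were 12 and 16. The share of 2-fold genes that were higher was 40.4%, but 23.9% on deposited TPM, with 251 higher and 800 lower. The median of all genes was -0.03, -0.13 with library totals alone and -0.29 on deposited TPM, and the factors lay further below 0 than that under each. Longer transcripts were lower in the paraquat library: the median log2 ratio went from 0.38 in the shortest decile of genes to -0.20 in the longest. Of the 20 genes named as highest or lowest, 8 share at least 20% of their sequence windows, such as Echdc1 with 15 against 143 counts and -0.56 when summed with its partner. Of 32 lists, 6 lay outside the central 95% of random lists, 2 with the length trend removed, and the other 26 had medians from -0.21 to 0.36.

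**Figure D4:**
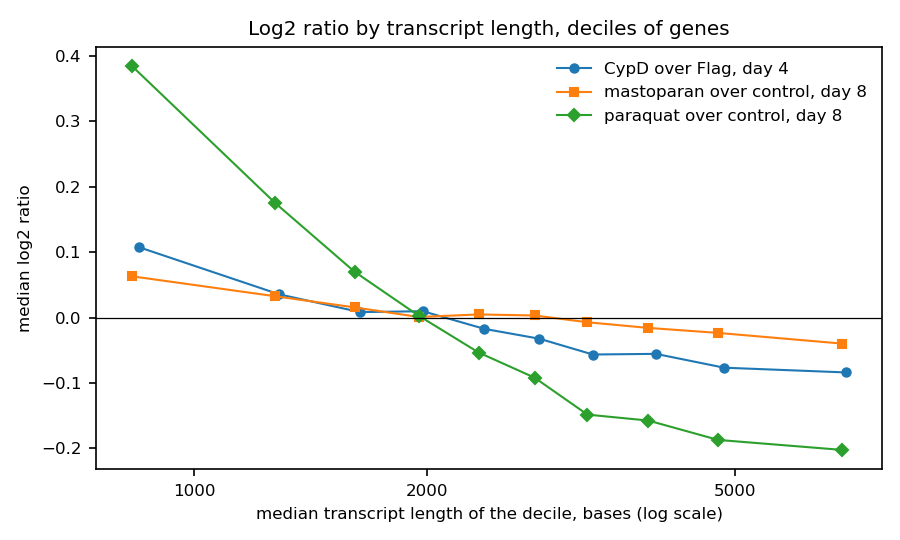
Median log2 ratio in deciles of genes by transcript length in bases on a log axis, for CypD over Flag, mastoparan over control and paraquat over control, among genes with at least 5 CPM and under 20% shared sequence; no error bars are drawn. The difference between the shortest and the longest decile is 0.59 for paraquat, 0.19 for CypD and 0.10 for mastoparan.

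Mastoparan and paraquat are structurally unrelated, and their libraries were also set against each other. The factors were higher in the mastoparan library, with a median log2 ratio of 0.76 (range 0.66 to 0.93 over the 4 genes, percentile 99.99), Klf4 1.91-fold (1.81 to 2.01), Sox2 1.73-fold (1.61 to 1.85), Myc 1.66-fold (1.57 to 1.75) and Pou5f1 1.58-fold (1.52 to 1.64). Fam221b had 0 against 165 counts, at least 67.9-fold lower in the mastoparan library, an uncertain value given its shared sequence. Ipo7 had 141 against 20 counts (5.71-fold higher, 3.56 to 9.63) and the cohesin regulator Pds5a 40 against 9 (3.6-fold, 1.72 to 8.44). The tight-junction gene Cldn7 was 3.21 times lower (1.73 to 6.27), and the polarity gene Pard6a 3.38 times lower (1.96 to 6.05). Of 39 G2/M genes 32 were above 0 (median 0.14, interval 0.04 to 0.26, percentile 98.99), with the cytokinesis gene Ect2 at 0.94 and Kif11 at 0.74. Hypoxia targets were above 0 in 17 of 20 cases (median 0.23, interval 0.05 to 0.35, percentile 99.99), with Vegfa at 0.49 and the lysyl oxidase family gene Loxl2 at 0.54. Fibroblast genes had a median of 0.12 (percentile 99.4), with Dcn at 1.01 and Col3a1 at 0.57. NRF2 and oxidative-stress genes were below 0 in 23 of 35 cases (median -0.12, percentile 6.06). Respiratory chain genes had a median of -0.34 (percentile 0.00) and Polycomb regulators one of 0.18 (percentile 99.4), which were at percentiles 50.5 and 86.8 with the length trend removed. With both the length and GC trends removed the hypoxia median was 0.09 (percentile 96.8) and the fibroblast median 0.06 (percentile 96.4). Across 13651 genes, 471 were at least 2-fold higher in the mastoparan library and 377 at least 2-fold lower, against 278 and 225 from noise. The share higher was 55.5%, and 69.0% on deposited TPM, where 696 were higher and 312 lower and the median of all genes was 0.23. Of 20 named genes, 9 share at least 20% of their sequence windows.

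The mastoparan and paraquat comparisons use the same control library, so their overlap was set beside simulations with no effect. There were 89 genes at least 2-fold higher in both, such as Fbxl22, and 71 at least 2-fold lower in both. Unchanged groups gave means of 71.7 and 40.3 from counting noise, and 149 and 84.6 with a further coefficient of variation of 0.2 between libraries. The value of 0.2 was not estimated from these libraries and overstates their variation. With a minimum of 5 CPM it gave a covariance of 0.112, above the squared SD of 0.286 for mastoparan over control. Its overlaps are therefore no realistic bound. Independent lists of the same sizes would share 5.07 and 10.7 genes. Pearson's r across genes was 0.376 against 0.447 from counting noise and 0.474 with the further variation. The covariance was 0.0925 against 0.0651 from counting noise, a difference of 0.0274, and against 0.145 with the further variation. In this main setting much of the excess over independent lists thus arises from counting noise around a shared control, with no treatment effect. Counting noise gave a smaller part in settings with less weight on low counts. With a minimum of 5 CPM, 17 genes were higher in both and 5 lower, against noise means of 4.47 and 1.45. With a pseudocount of 2 CPM there were 15 and 24, against 3.27 and 2.2. The part beyond counting noise cannot be split with 1 control library.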

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

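The tests of the factors with both trends removed, of a common fold of the factors, of counting noise among the 2-fold genes and of random partner genes, and the leaving out of length and GC trends, were chosen only after the results were seen. The deposited FPKM column, which no comparison used, summed to 807207 in the paraquat library and 724805 in the mastoparan library, above 710422 in the day-8 control. It summed to 698185 in the CypD library, above 679025 in the Flag library.

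The pattern behind the paraquat sum is that longer transcripts were lower in that library, with a difference of 0.59 in log2 ratio between the shortest and longest decile of genes. Thinning the control to the depth of the paraquat library, 80.4% of its counts, gave a difference of -0.000416 (SD 0.00380). Thinning takes the same share of reads from every gene, so a value near 0 was foreseeable. It shows only that evenly lost reads give no such trend, and says nothing further about the paraquat library. Leaving out 281 genes of short housekeeping families left 0.556, which argues against a difference in those families alone. Shorter RNA or library fragments may still be the source: of 4653 genes whose weighted transcript length differed, 53.6% (52 to 55) were shorter in the paraquat library, against 49% (48 to 51) of 4841 in the mastoparan library. That share lies between the bounds set for either answer, so RNA quality and the paraquat treatment itself, which was not tested, cannot be told apart with 1 library.

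The pattern a biologist may most want to follow is that Klf4, Sox2, Myc and Pou5f1 were all lower in the paraquat library. With the length and GC trends removed their median log2 ratio was -0.92, from -0.75 to -1.07 over the 4 genes. This argues against those trends at the annotated gene lengths, but the outcome was foreseeable. The lowest median of a length decile was -0.20, against -0.82 for the factors before removal. The lengths of any introduced copies were not given. Among 6 scalings the median nearest to 0 was -0.78 and the farthest -1.12, which argues against the choice among these scalings. That outcome was foreseeable too, because the median of all genes lay only between -0.29 and 0.02 under them. Less RNA from introduced copies, by dose or share of transduced cells, stays open: the 4 log2 ratios spanned 0.43, wider than a common fold would give, but no factor was higher, and copies cannot be told apart in gene tables. An action of paraquat on these genes was not tested and stays open as well.

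Many of the largest folds were in genes that share sequence with another gene. They made up 33 of 69 cases (47.8%) past 2-fold at 20 CPM or more over the 3 comparisons with a control, against 6.81% of all cases at that level. A case is a gene in a comparison, so a gene can count more than once. Counting noise alone gave 0.59 of those 69, which argues against counting error alone; variation between replicate libraries was not measured. Summed with its closest partner gene, the median absolute log2 ratio of the 33 was 0.22, from 1.41 before, and 25 were under 0.5. Part of that drop comes from summing alone: with random genes of the partner's level the median was 0.519 (95% of 1000 draws from 0.407 to 0.623), and 0 draws were as low as 0.22. In 25 of the 33 cases the partner differed in the opposite direction. The lower median with the closest partner is consistent with reads divided differently between near-identical genes, a candidate explanation found and tested on the same data. No biological explanation was tested for these genes.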

How the results depend on the processing

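The removal of length and GC trends and the leaving out of shared-sequence genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason leaving out a replicate was not possible. Of the ratios of named genes under the alternatives, 1217 stayed within their counting interval, widened where needed to hold the main value. Another 40 moved outside it and 1 changed sign. Sign changes were counted only for genes whose interval excluded no difference. List medians were followed only for lists outside the random range in the main setting. Of these 269 stayed within their interval, 26 moved outside it and 4 changed sign.

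The number of 2-fold genes moved with the filter and the pseudocount, which by construction admit or damp genes with few counts. With no filter it was 1490 for CypD against Flag, 1443 for mastoparan against control, 1756 for paraquat against control and 1788 for mastoparan against paraquat, where the main numbers were 503, 517, 804 and 848. With a minimum of 5 CPM it was 72, 73, 241 and 219, and with a pseudocount of 2 it was 153, 119, 311 and 323. With a pseudocount of 0.1 it was 787 for mastoparan against control. The number of lists outside the random range was 3 for mastoparan and 10 for paraquat against control on deposited TPM, where the main numbers were 7 and 6. With the length and GC trends removed it was 2 for CypD against Flag, 4 for mastoparan against control and 3 for mastoparan against paraquat. With the length trend alone removed it was 2 for paraquat against control. The cause was not tested.

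For CypD against Flag, Galnt2 was at 0.14 on deposited TPM, from -1.95. The fibroblast list was at 0.000699 with the length trend removed and 0.0125 with both trends removed, and the respiratory chain list at -0.00130 with both removed. For paraquat against control the NRF2 list was at -0.19 on deposited TPM. For these the cause was not tested. The correlation of the 2 day-8 comparisons ranged from 0.372 to 0.384 under its alternatives. A true 2-fold difference sat at the threshold and passed it in 42.0% to 54.0% of simulated genes over the comparisons, while a true 3-fold difference passed in 96.0% to 100%.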

Other observations

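The comparison of the day-8 control with the day-4 Flag library was chosen after seeing the data, while the test of the direction of the paraquat library was set before its result was seen. The day-8 control and the Flag library differ in day, in construct and in any batch, which cannot be separated. Epithelial genes were higher at day 8 in 30 of 30 measured cases, with a median log2 ratio of 2.16 (interval 1.60 to 2.63). The keratin gene Krt7 had 165 counts against 0, at least 45.2-fold higher, the claudin gene Cldn4 had 52 against 1, and the epithelial splicing regulator Esrp1 had 45 against 1. Keratinocyte markers were at least 1.5-fold higher in 13 of 14 cases, among them the cornified envelope gene Sprr1a with 118 against 6 counts (log2 ratio 3.76). Hypoxia targets were at least 1.5-fold higher in 15 of 20 cases (median 1.00) and glycolysis genes in 13 of 22 (median 0.77, interval 0.31 to 1.00), with the glucose transporter gene Slc2a1 at 2.35 and Aldoc at 2.64. The mitophagy receptor gene Bnip3 was at 2.04. S-phase genes were at least 1.5-fold lower in 20 of 35 cases (median -0.68), and 39 of 39 G2/M genes lay below 0 (median -0.57). The immediate-early gene Fosb had 76 against 481 counts (log2 ratio -2.92). Across 13540 genes, 1334 were at least 2-fold higher and 535 at least 2-fold lower, against 240 and 199 from counting noise.

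A hypothesis was that the paraquat library may lie behind the control along the day-4 to day-8 change. Among genes with a mean of at least 20 CPM over those libraries and under 20% of shared sequence, the 250 at least 2-fold higher in the mastoparan day-8 than in the Flag day-4 library had a median log2 ratio of paraquat over control of 0.049 (0.020 to 0.074) with the length trend removed. The 99 at least 2-fold lower, under the same limits, had a median of -0.11 (-0.18 to -0.02). Both medians are opposite to a library that lies behind, so for these genes as a set the test argues against the hypothesis. The intervals are over genes, which are not replicates, and variation between libraries was not measured. Lists higher at day 8 were mixed: with the length trend removed, paraquat over control had a median of -0.06 for hypoxia targets and 0.05 for epithelial genes.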
